A study of Mus musculus with 4 samples.

How the data were processed

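The data were 4 droplet libraries made with the 10x Genomics 3′ chemistry from sorted CD45.2+ leukocytes of the intraepithelial layer of uninfected C57BL/6 mice, 1 library per tissue, per the labels. The tissue labels name stomach, small intestine, cecum and colon; the extraction protocol text is the same in all 4 records and mentions colons only, and the tissue labels were used. The deposited matrices held UMI counts per gene symbol and cell barcode, all whole numbers, and were read as raw counts with no further normalisation. The submitters' processing notes name Cell Ranger and Seurat 3.0.0 with the mouse genome build GRCm38 (mm10). Each library listed its own set of symbols: 16500 were listed in any library and 13102 in all 4. No symbol of a ribosomal protein gene (Rpl or Rps) and no mitochondrial symbol was listed, so shares of mitochondrial UMIs were not analysed here and the limit of 10% set for them removed no cell. Gene positions were taken from an annotation of GRCm38.p6 by symbol, which placed 15985 symbols (96.9%) and 211 of the 212 genes named or held in the lists.

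Barcodes with at least 200 listed genes were kept, which removed 5 of 14378. Scrublet (run within scanpy, expected doublet rate 3%) called 13 further barcodes, 0.0904% of the total, which is far below the expected rate; the calls were removed, and doublets were in effect not filtered. The 14360 cells of all libraries were clustered together without batch correction: counts scaled to 10000 per cell and log-transformed, 2000 highly variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0. This gave 27 clusters. A cluster was named T-like when at least 50% of its cells carried a UMI of Cd3d, Cd3e or Cd3g; the share was 92.1% or more in the 12 T-like clusters and at most 25% in any other. Other clusters were named from fixed marker genes when at least 3 markers of the class were at least 2-fold above the cells outside that class, and when the 10 leading genes of the cluster held at least as many markers of the class as of any other. Class names end in "-like" because they rest on transcripts alone. The dendritic-like class was led by Siglech.

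For each class and library, UMIs were summed over cells and given as CPM (counts-per-million of the summed total), with exact Poisson intervals. Ratios between libraries carry exact conditional binomial intervals, and shares of cells carry exact (Clopper-Pearson) binomial intervals, all at 95%. These intervals cover counting error only: with 1 library per tissue there was no replicate check, no p-value was computed, and tissue, animal, library and sequencing run could not be separated. For a count of 0 the upper limit is that of 3 counts, and a ratio against 0 is a lower bound computed with 3 counts in the class and library at 0. A gene entered a comparison when it was listed in both libraries, reached 50 CPM in either and had at least 20 UMIs in total. The genes named for each T-like comparison were the 12 with the highest and the 12 with the lowest ratio whose interval excluded 1, together with 18 genes of intraepithelial lymphocyte biology fixed in advance; ribosomal, mitochondrial, immunoglobulin, hemoglobin, sex-linked and unnamed transcripts and receptor V, D and J segments were passed over. A gene whose level in the higher library was under 20% of that in another class of the same library was set apart as possible free RNA. Other classes were compared by the same rule, with 5 genes in each direction, where each library held at least 100 cells of the class; only B-like cells of cecum and colon met this.

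The gene lists were fixed in advance. For each list the median log2 ratio of its measured genes, with a gene at a count of 0 entered at its bound, was placed among 10000 random lists matched on expression level, and members at least 1.5-fold higher or lower were counted. Receptor transcripts were scored as the share of cells with at least 1 UMI after thinning each cell to 1000 UMIs, since median depth differed between libraries. The comparison of summed counts was checked on simulated counts in which 100 genes were changed 4-fold and 100 were changed 2-fold. The median estimates were 4.03-fold and 2.00-fold for stomach against small intestine, 4.04-fold and 2.00-fold for small intestine against colon, and 4.02-fold and 1.99-fold for cecum against colon. The interval held the true ratio for 93% to 98% of changed genes and held 1 for 94.4% to 95.2% of unchanged genes. The simulated counts were drawn from the Poisson model that the intervals assume, with no spread between cells or libraries. The check therefore covers the calculation only, and does not show that the intervals hold for real cells.

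The tissue comparisons, filters, clustering settings, class markers, gene lists, rules for naming genes and most alternatives were set before the data were examined. The following were chosen afterwards: clusters in which at least 50% of cells carried transcripts of a lineage other than their class were left unnamed (B cell transcripts in plasma-like cells were allowed), which applied to clusters 1 and 14; markers were compared with cells outside the class rather than with all other cells, against which T-like cluster 12 was led by NK receptor genes; the median absolute log2 ratio replaced a count of genes at a 2-fold difference as the summary of a comparison; list members were counted by size alone; and the set of 12 genes low in all stomach classes was defined by a log2 ratio of −2 or less in 4 classes. Some genes that these rules named are not reported here. Alternatives chosen after seeing the data are named as such where their values are given.

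Computations used Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, python-igraph 0.11.9, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16 for TMM scaling.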

Results

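The libraries held 14378 barcodes, of which 3192 from stomach, 3170 from small intestine, 4238 from cecum and 3760 from colon were kept. Total depth was 9022713 UMIs in the stomach library, 11750691 in small intestine, 8568438 in cecum and 12988676 in colon. The median was 2304 UMIs per barcode in stomach, 2475 in small intestine, 1707 in cecum and 2983 in colon. The lowest barcode held 280 UMIs in stomach, 361 in cecum and 224 in colon, but 1581 in small intestine, so the other libraries held shallower cells than that one. The labels give no batch other than the library itself.

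The first comparison asked which leukocyte classes made up the sorted CD45.2+ cells of each tissue; ranges in parentheses are 95% intervals throughout. T-like cells made up 89.5% (88.4–90.4%) of the colon library, 81.0% (79.8–82.2%) of cecum and 77.1% (75.6–78.6%) of small intestine, but 7.80% (6.89–8.79%) of the stomach library, or 249 cells. The stomach library was made up mainly of mast-like cells, the granulocytes that store proteases and histamine, at 60.7% (59.0–62.4%); their share was 2.02% in small intestine, 0.661% in cecum and 0.106% in colon. NK/ILC1-like cells, innate lymphocytes that kill or make interferon gamma, formed 13.1% (12–14.3%) of the stomach library against 1.55%, 1.68% and 2.23% in small intestine, cecum and colon. Macrophage-like cells formed 10.9% (9.87–12.1%) of the stomach library against 2.21%, 0.590% and 1.17%. ILC2-like cells, innate lymphocytes that make type-2 cytokines, formed 1.57% of the stomach library, 0.221% of small intestine and 0.0266% of colon; cecum had 0 of 4238 cells, which allows a share of up to 0.0708%.

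B-like cells were most frequent in cecum, at 14.9% (13.9–16.0%), against 5.43% (4.72–6.20%) in colon, 2.57% in stomach and 2.40% in small intestine. Antibody-secreting plasma-like cells formed 6.50% (5.67–7.41%) of the small intestine library and 0.125%, 0.307% and 0.0798% of the stomach, cecum and colon libraries. Dendritic-like cells formed 6.85% (5.99–7.78%) of the small intestine library, with 0.157% in stomach, 0.613% in cecum and 0.585% in colon. Epithelial-like cells, which the sort should remove, were 0 of 3192 cells in stomach, which allows a share of up to 0.0940%, and 0.568%, 0.0472% and 0.106% in small intestine, cecum and colon. Cells left unnamed formed 2.98%, 0.568%, 0.212% and 0.798% of the stomach, small intestine, cecum and colon libraries. Among cells with at least 1581 UMIs, a limit chosen after seeing the data, the B-like share of cecum was 6.01%, and over the settings run the T-like share of the stomach ranged from 4.89% to 9.84%.

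**Figure D1:**
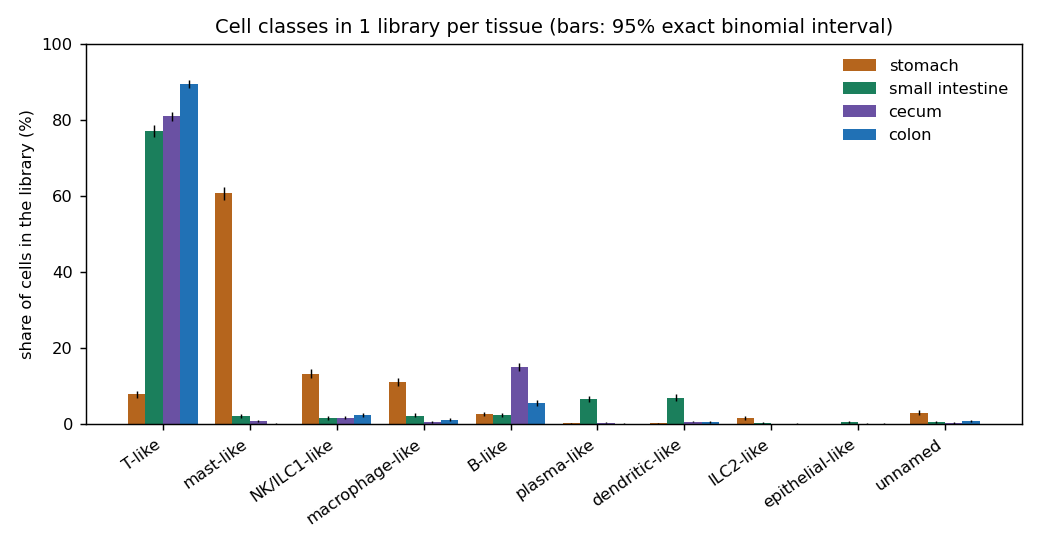
Share of kept cells in each library (vertical axis, %) for each cell class (horizontal axis), with 1 bar per tissue and 95% exact binomial intervals. Mast-like cells reach 60.7% in the stomach library, and T-like cells reach 77.1% to 89.5% in the other 3.

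Receptor and co-receptor transcripts were compared among T-like cells thinned to 1000 UMIs, to ask which lineages the T-like cells of each tissue belonged to. Trdc, the constant region of the delta chain of the gamma-delta receptor (chromosome 14, 54142851 to 54146108; positions are in GRCm38.p6), was seen in 54.0% (52.0–56.0%) of small intestine T-like cells, against 20.7% (19.3–22.1%) in colon, 14.1% (9.99–19.0%) in stomach and 11.6% (10.5–12.7%) in cecum. Cd8a, the co-receptor alpha chain that most intestinal intraepithelial T cells carry, followed with 67.6% (65.7–69.4%) in small intestine, 41.6% (39.9–43.3%) in colon, 26.9% (25.4–28.4%) in cecum and 12.4% (8.62–17.2%) in stomach. Cd8b1, the beta chain of conventional cytotoxic T cells, was highest in stomach at 18.5% (13.9–23.9%), against 3.39% in small intestine, 3.03% in cecum and 2.51% in colon. Cd4, the helper co-receptor, was seen in 8.43% (5.30–12.6%) of stomach T-like cells, 2.04% in small intestine, 0.742% in cecum and 1.04% in colon. Trac, the alpha-chain constant region, was seen in 49.8%, 40.7%, 54.0% and 51.7% of stomach, small intestine, cecum and colon T-like cells. A UMI of Trac, Trbc1 or Trbc2 was seen in 89.2%, 92.2%, 96.9% and 96.0%. In small intestine this group overlaps with the 54.0% of cells with Trdc, so the combined share does not tell the lineages apart. A UMI of Foxp3, the factor of regulatory T cells, was seen at this depth in 0 of 249 stomach cells (2 without thinning), which sets no limit on the share of cells that express it, and in 0.286%, 0.119% and 0.119% of small intestine, cecum and colon cells.

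B-like cells, which should lack these transcripts, gave the background, which was not split between free RNA and doublets. The B-like share with Trdc was 13.2% in small intestine, 2.47% in stomach, 0.933% in cecum and 0.980% in colon. For Cd8a it was 14.5% in small intestine, 7.84% in colon, 1.87% in cecum and 0 of 81 cells in stomach. The small intestine values for Cd8b1 and Cd4 could not be told from the B-like background of 2.63% and 2.63%, which rests on 76 cells. This does not show that such cells were absent. A T-like cluster with Cd4 among its leading genes held 147 small intestine cells. Foxp3 in cecum, with 0.187% in B-like cells, could not be told from background either. The background for Trac, Trbc1 or Trbc2 in small intestine B-like cells was 34.2%. Before thinning, the median depth of T-like cells was 2462 UMIs in stomach, 2316 in small intestine, 1751 in cecum and 3000.5 in colon, against 1943.5, 3167, 1252 and 1992.5 in B-like cells. With at least 2 UMIs required, the Trdc share was 33.1% in small intestine, 13.5% in colon, 12% in stomach and 7.12% in cecum.

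**Figure D2:**
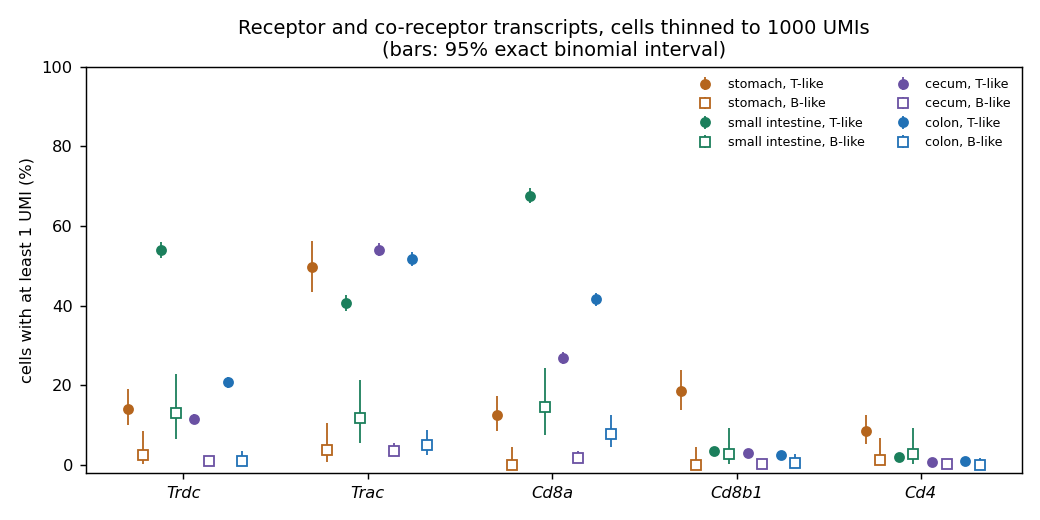
Share of cells with at least 1 UMI of each receptor or co-receptor transcript after thinning to 1000 UMIs (vertical axis, %), for T-like cells (filled) and B-like cells (open) of each tissue, with 95% exact binomial intervals. Trdc and Cd8a are highest in small intestine T-like cells, at 54.0% and 67.6%, and Cd8b1 in stomach T-like cells, at 18.5%.

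T-like cells of stomach and small intestine were compared to ask how T cells of the gastric layer differ from those of the small intestine. Gzma, a granule protease of killer cells (chromosome 13, 113093824 to 113100981), stood at 673 (614–737) CPM in stomach and 28070 (27941–28199) in small intestine, 41.7-fold (38.1–45.7) lower. Ccr9, a chemokine receptor that guides lymphocytes to the small intestine (chromosome 9, 123767211 to 123783457), was 20.7-fold (12.1–39.0) lower, at 18.5 against 385 CPM. Itgae, the integrin alpha E chain that binds E-cadherin on epithelial cells (chromosome 11, 73090505 to 73147449), was 7.26-fold (5.92–9.0) lower. Conversely S100a4, a calcium-binding protein of motile and memory cells, was 144-fold (113–187) higher, and Ifng, which encodes interferon gamma (chromosome 10, 118441046 to 118445894), was 10.6-fold (9.43–12) higher, at 820 against 77.1 CPM.

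The comparison covered 249 stomach cells with 700822 UMIs and 2445 small intestine cells with 6449808 UMIs, and the median absolute log2 ratio over 4554 genes was 0.44. Of these T-like cells, 73.9% in stomach but 6.01% in small intestine lay in the same cluster. The ratios thus include differences in cluster shares. Among the other genes with the highest ratios were S100a6 (63.4-fold, 54.7–73.8), Ctla2a (45-fold, 38.3–53.1), Ly6c2, a surface protein of memory T cells (75.5-fold, 58.1–99.7), Nrp1 (212-fold, 69.5–1052), Anxa1 (163-fold, 52.7–813), Tmem176a (65.0-fold, 38.3–118) and AB124611 (74.8-fold, 35.8–180). So were Ramp1, a subunit of the receptor for calcitonin gene-related peptide (60.2-fold, 39.0–96.8), and Sema4a (38.7-fold, 24.6–63.2). Krt83 (223-fold, 84.4–836) is also a leading gene of the NK/ILC1-like cluster. Clps, which encodes pancreatic colipase, was at least 847-fold higher, but all 276 UMIs came from 1 cell. The genes with the lowest ratios included Scand1 (46.2-fold lower, 21.2–126), Cited4 (42.1-fold, 16.4–155), Taf10, a subunit of general transcription complexes (27.0-fold, 12.4–73.7) and Ncf1 (17.1-fold, 9.28–35.7). Others were Cfap126 (15.7-fold, 5.33–76.3), Dapk3 (15.7-fold, 5.33–76.3), Adrb1, a beta-adrenergic receptor (15.2-fold, 6.97–41.6), Smap1 (15.2-fold, 7.98–33.3) and Tspan9 (14.9-fold, 7.56–34.7). Mei1 was 34.8-fold (9.60–288) lower on 2 stomach counts. Scand1, Taf10, Dapk3 and Smap1 were also low in stomach NK/ILC1-like, B-like, macrophage-like and mast-like cells; in NK/ILC1-like cells their log2 ratios to small intestine were −4.64, −4.47, −3.63 and −2.80. Many of the lower values in stomach were shared with other classes.

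Of the genes fixed in advance, Gzmb (10.5-fold, 9.23–11.9), Cd8a (6.91-fold, 5.92–8.11), Ahr, the aryl hydrocarbon receptor that intraepithelial T cells need to persist (4.62-fold, 3.37–6.53), Trdc (3.30-fold, 2.92–3.74), Cd160 (1.68-fold, 1.49–1.89) and Fcer1g (1.64-fold, 1.54–1.76) were lower in stomach. Cd8b1 (7.96-fold, 6.71–9.44), Cd4 (3.20-fold, 2.27–4.44), Trac (1.55-fold, 1.43–1.69) and Klf2, a factor that keeps T cells in circulation (2.72-fold, 2.34–3.15), were higher. Il17a, the cytokine interleukin 17A, was at least 383-fold higher, with 125 UMIs against 0, of which 62.4% came from 1 cell. Without that cell, a step chosen after seeing the data, the log2 ratio was 7.17 in place of 8.58. The same step moved Gzma from −5.38 to −7.18, since 1 cell held 71.4% of its stomach UMIs. Foxp3 had 2 stomach counts and a ratio of 1.23 (0.136–5.28), and Gpr15, a receptor for homing to the colon, had 0 and 2 counts, too few for a ratio.

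By list, genes of circulating or naive T cells were higher in stomach: 14 of 16 measured members were at least 1.5-fold higher and 1 lower, with a median log2 ratio of 2.21 above every random list. Examples were Ly6c2, Dapl1 (36.8-fold, 20.2–71.6) and Klf2. The type 17 effector list had 9 of 10 members higher and 1 lower (median 4.99), with Il17a, Tmem176a and Cd163l1 (36.8-fold, 20.2–71.6) among them. In the homing and chemokine receptor list 10 of 15 members were higher and 4 lower (median 1.73). Ccr2, a receptor of inflammatory homing (29.6-fold, 21.1–42.2), and Cxcr4 (20.9-fold, 14.3–30.9) were higher while Ccr9 was lower. Of type 1 effector genes 9 of 16 were higher and 1 lower (median 0.70). Tnf (16.6-fold, 11.5–24.3) and Ifng were higher and Ccl5 (4.75-fold, 4.61–4.90) was lower. Of immediate early and dissociation response genes 22 of 31 were higher and 3 lower (median 1.18). Among them were Nfkbia (9.23-fold, 8.65–9.86), Dnajb1 (6.42-fold, 6.05–6.81) and Hspa1a (5.80-fold, 5.54–6.06), whose reads are hard to tell from Hspa1b. Interferon response genes were higher for 21 of 32 and lower for 1 (median 1.10), with Ifit3 at 10.4-fold (7.68–14.2) and Slfn5 at 12.9-fold (8.56–19.7). All 5 of these last lists also lay above every random list. A T-like cluster led by Ifit3 and Ifit1 held 7.23% of stomach and 1.55% of small intestine T-like cells, and interferon genes were not compared within clusters.

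Intraepithelial residency genes were lower in stomach, 12 of 20 against 4 higher (median −0.90, below every random list), with Itgae, Cd8a and Gpr55 (9.41-fold, 4.75–21.9) as examples. The cytotoxic granule list had 6 of 14 lower and 2 higher (median −0.26, percentile 5.89). The checkpoint receptor and exhaustion list had 7 of 13 lower and 2 higher (median −0.80, percentile 0.25). Lag3, an inhibitory receptor, was 9.61-fold (6.06–16.3) lower and Pdcd1, another, 8.59-fold (5.50–13.4) higher. The fatty acid and cholesterol list had 12 of 22 lower and 2 higher (median −0.62, percentile 0.230), including Insig1 (3.65-fold lower, 2.65–5.15) and Hmgcs1 (3.43-fold lower, 2.60–4.63). The aryl hydrocarbon receptor list had 4 of 6 lower (median −1.38, percentile 0.140). The NK-type receptor list had 15 of 27 higher and 7 lower (median 0.79, above every random list), with Klrk1 32.0-fold (26.0–39.5) higher. NK/ILC1-like cells, which carry these receptors, made up 13.1% of that library. The stomach T-like class held 167 cells with Scrublet calls kept and 190 with at least 500 genes, where the NK/ILC1-like share was 15.2% and 14.9%. Whether the cells that left one class joined the other was not traced, so NK-type values in stomach T-like cells are uncertain. The Klra genes among them are near-identical and their counts uncertain. Median log2 ratios of the remaining lists were 0.88 for type 2 effector, 0.74 for regulatory T cell and 0.54 for proliferation. They were 0.49 and 0.88 for antigen presentation class I and II, 0.28 for oxidative phosphorylation, 0.40 for glycolysis and hypoxia and 0.10 for TGF-beta response; the medians for oxidative phosphorylation and TGF-beta response lay inside the central 95% of random lists.

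Transcripts of other cells were measurable in these T-like cells: the mast cell protease Mcpt2 stood at 183 CPM in stomach and 12.7 in small intestine. Igkc, Igha, Jchain, Scin, Epcam, Lmna, Tmem176b, Ncr1, Sdc4 and Ifitm2 were set apart as possible free RNA. With T-like cells chosen by marker UMIs (314 stomach and 2060 small intestine cells) the log2 ratio of Nrp1 was 4.43 in place of 7.73. It was 4.25 for Ly6c2 in place of 6.24, 6.44 for S100a4 in place of 7.17 and 4.18 for Ramp1 in place of 5.91. With the Scrublet calls kept, Itgae was at −3.67 in place of −2.86, Cd160 at −1.66 in place of −0.75 and Ifit3 at 2.51 in place of 3.38, while Klra9 and Gzmc, of the NK-type and cytotoxic lists, turned direction. Ube2c and Nusap1 of the proliferation list and Cd74 of the class II list turned direction with T-like cells chosen by marker UMIs, and Trac did so among cells with a Trdc UMI, at −1.43 in place of 0.63. Among the 40 stomach cells with a Trdc UMI the log2 ratio was −2.17 for Ccr9 in place of −4.37, −3.05 for Gzma in place of −5.38, −1.86 for Gzmb in place of −3.39 and 0.42 for Cd8b1 in place of 2.99. Among the 51 with a Cd8a UMI it was −2.83 for Ccr9, −3.27 for Gzma and 4.78 for Cd8b1.

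T-like cells of small intestine and colon were compared to ask how intraepithelial T cells of these parts of the gut differ. Genes of circulating or naive T cells were lower in small intestine, at least 1.5-fold for 14 of 18 measured members. Gzma stood at 2085 (2059–2112) CPM in colon and was 13.5-fold (13.3–13.6) higher in small intestine. Ccr9 was 5.91-fold (5.44–6.42) higher at 385 against 65.1 CPM, and Itgae 3.57-fold (3.42–3.73) higher at 974 against 273. S1pr1, the receptor that lets lymphocytes leave tissue (chromosome 3, 115710433 to 115715055), was 9.50-fold (7.29–12.6) lower in small intestine, at 8.99 against 85.4 CPM. T-like clusters 9 and 16, both with S1pr1 and Lef1 among their leading genes, held 15.6% and 3.39% of colon T-like cells. In small intestine they held 0.286% and 0.327%. The lower values of such genes thus include smaller shares of these clusters, and levels within clusters were not compared.

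The comparison covered 2445 and 3364 cells with 6449808 and 11458427 UMIs, and the median absolute log2 ratio over 4473 genes was 0.28. The other genes with the highest ratios were Gzmk (10.6-fold, 8.43–13.6), Itgad (9.19-fold, 7.59–11.2) and Prdm1, a repressor that promotes effector and resident T cells (7.63-fold, 6.18–9.50). They were followed by Plek (5.66-fold, 4.83–6.64), Maf (5.04-fold, 4.06–6.28), the chemokine gene Ccl4 (4.91-fold, 4.64–5.19), Stk32c (4.70-fold, 3.91–5.67), Cpd (4.49-fold, 3.86–5.23) and Hip1 (4.47-fold, 3.78–5.31). The other genes with the lowest ratios were Klra6 (5.89-fold lower, 5.09–6.85), Klra7 (5.83-fold, 5.26–6.48), Lef1, a factor of naive T cells (5.17-fold, 4.18–6.45), Ctla2a (5.11-fold, 4.38–5.99) and Gramd3 (5.01-fold, 4.17–6.06). Next came the adhesion receptor Cd2 (5.01-fold, 4.36–5.77), Il18r1 (4.87-fold, 3.78–6.35), Glipr2 (4.64-fold, 3.62–6.02), Klra1 (3.98-fold, 3.25–4.91), Klre1 (3.76-fold, 3.31–4.28) and Nfkbia (3.39-fold, 3.23–3.57). Near-identical Klra genes share reads, so their separate values are uncertain. Of the genes fixed in advance, Gzmb (3.01-fold, 2.95–3.08), Trdc (2.49-fold, 2.40–2.57), Cd4 (2.44-fold, 1.88–3.16), Cd8a (1.85-fold, 1.80–1.90), Cd8b1 (1.48-fold, 1.26–1.73) and Fcer1g (1.34-fold, 1.31–1.36) were higher in small intestine. The shares of cells with Cd4 and Cd8b1 there could not be told from background. Klf2 (5.94-fold, 5.52–6.39), Ahr (1.49-fold, 1.40–1.57), Trac (1.44-fold, 1.39–1.5), Cd160 (1.39-fold, 1.34–1.44) and Ifng (1.25-fold, 1.12–1.39) were lower. Gpr15 was 27.0-fold (7.28–226) lower on 2 small intestine counts, Foxp3 had a ratio of 2.42 (1.04–5.83) on 15 and 11 counts, and Il17a had 0 counts in both.

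By list, 5 of 14 measured cytotoxic granule genes were at least 1.5-fold higher in small intestine and 0 lower (median log2 ratio 0.40, percentile 99.93 of random lists), with Gzma, Gzmk, Gzmb and Cst7 (2.0-fold, 1.89–2.12) as examples. Residency genes were higher for 8 of 21 and lower for 1 (median 0.46, above every random list). Ccl5, a chemokine of killer cells, was 3.66-fold (3.63–3.69) higher and Xcl1 2.34-fold (2.26–2.42) lower. Genes of circulating or naive T cells were lower for 14 of 18 and higher for 0 (median −2.28, below every random list), with S1pr1 and Lef1 as examples. Ly6c2 and Klf2 in this list were set apart as possible free RNA. NK-type receptors were lower for 14 of 27 and higher for 5 (median −0.63, below every random list). Interferon response genes were higher for 17 of 32 and lower for 1 (median 0.62, above every random list). Gbp2 (2.68-fold, 2.32–3.10) and Stat2 (2.30-fold, 2.01–2.65) were examples. Fatty acid and cholesterol genes were higher for 10 of 22 and lower for 0 (median 0.41, percentile 99.95). They included Sqle (2.57-fold, 2.27–2.91) and Hmgcs1 (2.43-fold, 2.25–2.62). Checkpoint genes were higher for 5 of 13 and lower for 2 (median 0.51, percentile 99.9), with Lag3 at 3.65-fold (3.35–3.98) higher.

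Oxidative phosphorylation genes were lower in small intestine for 12 of 45 (median −0.32, percentile 0.0350), and class II antigen presentation genes for 5 of 9 (median −0.59, percentile 0.510). Cd74 of the class II list turned direction with Scrublet calls kept, at 1.10 in place of −0.55. The median was −0.30 for glycolysis and hypoxia (percentile 1.14), −0.32 for TGF-beta response (percentile 1.94), 0.32 for proliferation (percentile 98.5) and 0.22 for type 1 effector, all outside the central 95% of random lists. Inside the central 95% of random lists lay homing and chemokine receptor (0.17), type 17 effector (0.48), type 2 effector (0.24), regulatory T cell (0.06), immediate early and dissociation response (−0.07), antigen presentation class I (0.07) and aryl hydrocarbon receptor (0.07). The homing and aryl hydrocarbon receptor lists had means of the opposite sign, −0.16 and −0.47.

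Plasma cell transcripts were present in small intestine T-like cells, with Igkc at 288 CPM against 4.28 in colon. Igkc, Jchain, Lmna, Ly6c2, Scin, Klrk1, Itgax, Gas7, S100a6 and Klf2 were set apart as possible free RNA. Among T-like cells with a Trdc UMI alone, the log2 ratio was 2.39 for Gzma in place of 3.75, 1.65 for Ccr9 in place of 2.56, 0.64 for Maf in place of 2.33 and 0.54 for Gzmb in place of 1.59. In the same cells it was 1.96 for Gzmk in place of 3.41, 1.73 for Prdm1 in place of 2.93 and 0.87 for Ccl4 in place of 2.30. Among cells with a Cd8a UMI, Ifng was at 0.56 in place of −0.32.

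T-like cells of cecum and colon were compared to ask how these neighbouring parts of the large intestine differ. They differed less: the median absolute log2 ratio over 4314 genes was 0.17, with 3432 and 3364 cells and 6699775 and 11458427 UMIs. Pdcd1, which encodes the inhibitory receptor PD-1 (chromosome 1, 94038305 to 94052553), was 3.79-fold (3.12–4.61) higher in cecum, at 50.9 (45.6–56.6) against 13.4 (11.4–15.7) CPM. The heat-shock genes Dnajb1 (2.49-fold, 2.40–2.58), Dnaja4 (2.38-fold, 2.04–2.78), Hspb1 (2.38-fold, 2.03–2.78) and Hspa1a (2.37-fold, 2.31–2.44) were higher in cecum. A T-like cluster with Hspb1, Dnaja4 and Hspa1a among its leading genes held 15.3% of cecum and 6.42% of colon T-like cells. Levels of these genes within clusters were not compared. Gzmb (4.75-fold, 4.52–4.99) and Gzma (2.90-fold, 2.81–3.0) were lower in cecum, as was Cox7c, a subunit of cytochrome oxidase (chromosome 13, 86044798 to 86046795; 3.07-fold, 2.87–3.29).

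The other genes with the highest ratios were Sox4 (2.53-fold, 2.16–2.97), the stress-response kinase gene Sgk1 (2.44-fold, 2.18–2.74), Nrgn (2.41-fold, 2.05–2.83), Gadd45a (2.27-fold, 2.04–2.54), Cd6 (2.19-fold, 1.88–2.56), Ier5l (2.13-fold, 1.89–2.41) and Ramp1 (2.11-fold, 1.84–2.42). The other genes with the lowest ratios were the NK-type receptor gene Klra5 (3.90-fold lower, 3.52–4.32) and Fgl2 (3.86-fold, 3.37–4.44). They also included Smim27 (3.79-fold, 3.10–4.67), Cox7a2 (3.69-fold, 3.12–4.38), Mei1 (3.41-fold, 2.96–3.95), Sec61g (3.04-fold, 2.62–3.54), Polr2l (2.91-fold, 2.53–3.36), the histone gene Hist1h2ap (2.88-fold, 2.67–3.12) and Pet100, an assembly factor of cytochrome oxidase (2.86-fold, 2.51–3.28). Many of the lower values in cecum were shared with other classes: by a comparison chosen after seeing the data, the median log2 ratio over other classes was −1.77 for Cox7c, −1.38 for Smim27, −1.20 for Sec61g, −1.22 for Polr2l and −2.15 for Pet100. Of the genes fixed in advance, Cd8a (2.05-fold, 1.97–2.14), Trdc (1.73-fold, 1.64–1.82), Itgae (1.47-fold, 1.38–1.58) and Fcer1g (1.27-fold, 1.24–1.31) were lower in cecum, and Ifng (1.54-fold, 1.41–1.68) and Klf2 (1.36-fold, 1.32–1.41) were higher. The ratios of Ahr (0.998), Ccr9 (0.956), Gpr15 (0.980), Cd160 (0.943) and Trac (1.04) lay near 1. The intervals of Cd4 (ratio 1.24, 0.909–1.68), Cd8b1 (1.15, 0.976–1.36) and Foxp3 (1.87, 0.754–4.67) included 1. Il17a was at least 7.41-fold higher, with 13 UMIs in cecum and 0 in colon.

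By list, immediate early and dissociation response genes were at least 1.5-fold higher in cecum for 17 of 32 measured members and lower for 0 (median log2 ratio 0.61, above every random list). The list's median was 0.47 in NK/ILC1-like (71 and 84 cells), 0.54 in macrophage-like (25 and 44 cells) and −0.15 in B-like cells. Hsph1 (1.95-fold, 1.84–2.05) was among them beside Dnajb1 and Hspa1a. Oxidative phosphorylation genes were lower for 20 of 45 and higher for 0 (median −0.49, below every random list), including Ndufa3 (2.83-fold, 2.56–3.15) and Ndufa6 (2.79-fold, 2.36–3.30) of complex I. Proliferation genes were lower for 7 of 14 and higher for 0 (median −0.53, below every random list), including Mki67, a marker of dividing cells (2.02-fold, 1.74–2.36), Hmgb2 (1.75-fold, 1.59–1.92) and Stmn1 (1.64-fold, 1.40–1.92). Among cells with a Cd8a UMI, Mki67 was at a log2 ratio of −0.20 in place of −1.01. Class II antigen presentation genes were lower for 6 of 9 (median −0.92, below every random list). Its member Cd74, set apart as possible free RNA, turned direction with Scrublet calls kept, at 1.05 in place of −1.08. Residency genes were lower for 5 of 20 and higher for 1 (median −0.28, percentile 0.0200), with Xcl1 1.81-fold (1.75–1.86) lower. Checkpoint genes were lower for 4 of 13 and higher for 2 (median −0.31, percentile 0.205). Pdcd1 and Ctla4 (1.86-fold, 1.67–2.06) were the members that were higher. NK-type receptors were lower for 6 of 28 and higher for 3 (median −0.16, percentile 0.170). Fatty acid and cholesterol genes were higher for 5 of 20 and lower for 1 (median 0.28, percentile 99.99), with Insig1 1.87-fold (1.72–2.02) higher.

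Type 2 effector (median 0.67, percentile 99.6) and type 17 effector genes (0.40, 98.1) lay on the cecum side. Inside the central 95% of random lists lay cytotoxic granule (−0.09), circulating or naive T cell (0.07, with a mean of −0.03), homing and chemokine receptor (−0.07), type 1 effector (−0.05), regulatory T cell (0.18), interferon response (−0.05), antigen presentation class I (0.10), glycolysis and hypoxia (−0.06), aryl hydrocarbon receptor (−0.03) and TGF-beta response (0.22). The genes Lilrb4a, Lilr4b, Tubb2a and Ctsl were set apart as possible free RNA. Among cells with a Trdc UMI, Gzma was at a log2 ratio of −0.62 in place of −1.54. Hist1h2ap was at −0.94 in place of −1.53 with Scrublet calls kept. Cecum T-like cells were also shallower than colon cells, and the bound for Il17a was at a log2 ratio of 1.21 in place of 2.89 when cells were thinned to 1000 UMIs.

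**Figure D3:**
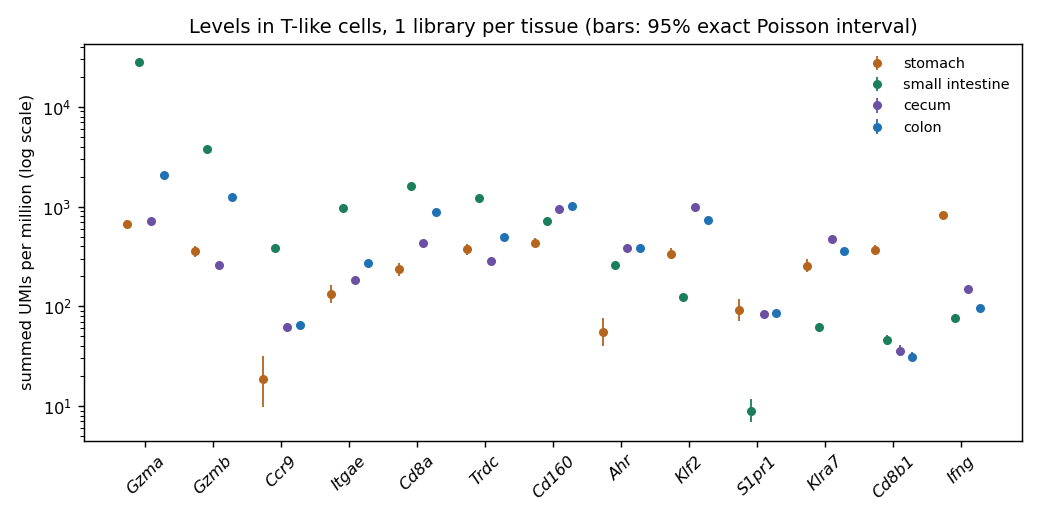
CPM in T-like cells (vertical axis, log scale) for 13 genes (horizontal axis) in each tissue, with 95% exact Poisson intervals. Gzma, Gzmb, Ccr9 and Itgae are highest in small intestine (28070, 3745, 385 and 974), where Klf2 and S1pr1 are lowest (124 and 8.99).

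**Figure D4:**
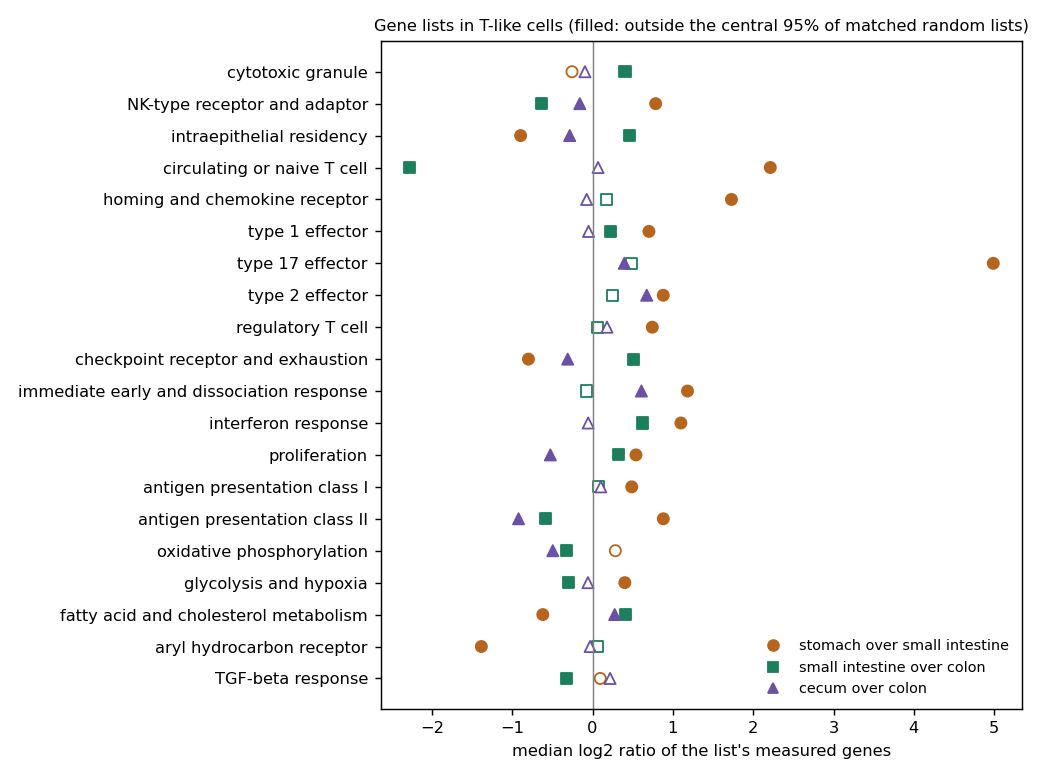
Median log2 ratio of each gene list's measured genes in T-like cells (horizontal axis) for 3 tissue comparisons, filled where the median lies outside the central 95% of 10000 matched random lists. The list of circulating or naive T cell genes is at 2.21 for stomach over small intestine and at −2.28 for small intestine over colon.

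For the other pairs of tissues the median absolute log2 ratio in T-like cells was 0.37 for stomach against cecum, 0.36 for stomach against colon and 0.32 for small intestine against cecum. The largest T-like cluster also differed by tissue, with leading genes taken against all other cells. Ratios taken over all T-like cells therefore include differences in cluster shares. In stomach, 73.9% of T-like cells were in a cluster with Maf, Icos, Izumo1r, Tnfrsf4, Cd40lg, Il17a and Cd4 among its leading genes. That cluster held 6.01% of small intestine, 2.62% of cecum and 1.72% of colon T-like cells. In small intestine, 41.8% of T-like cells were in a cluster with Gzma and Ccl5 among its leading genes. In cecum, 31.8% were in a cluster led by Cldn10 and Myl1, which also held 12.4% of colon T-like cells. In colon, 20.8% were in a cluster led by Gm156 and Klra5, which also held 16.3% of small intestine T-like cells.

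B-like cells were compared between cecum (632 cells) and colon (204 cells), the only other pair with enough cells. Cks1b, a cyclin-dependent kinase subunit, was 51.3-fold (9.04–2045) higher on 118 and 1 counts. Pclaf, which binds the replication clamp, was at least 43.2-fold higher at 265 CPM against 0. Smco4 (38.3-fold, 6.69–1529), Uhrf1 (36.1-fold, 6.30–1443) and Tpx2 (35.7-fold, 6.23–1426), each on 1 colon count, followed. Gzma (25.1-fold lower, 17.2–38.1), Gzmb (16.7-fold, 10.4–28.1), Hspb1 (16.1-fold, 6.28–52.6), Smim27 (6.27-fold, 3.05–13.9) and Cd8a (4.69-fold, 3.29–6.77) were the lowest. Gzma, Gzmb and Cd8a are T cell transcripts. The median absolute log2 ratio over 4307 genes was 0.32. A cluster of 73 B-like cells, 50 from cecum, 23 from small intestine and 0 from colon, had Mef2b and Rgs13 among its leading genes, both genes of germinal centre B cells. In it 75.3% of cells had a UMI of Mki67, Top2a, Pclaf or Birc5, against 4.34% in the other B-like cluster. Without that cluster, a choice made after seeing the data, the cecum counts were 7 for Cks1b, 1 for Pclaf, 12 for Smco4, 1 for Uhrf1 and 6 for Tpx2, and of their ratios only that of Smco4 (6.91-fold, 1.02–295) had an interval that excluded 1.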

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

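The 4 results below were noticed after the data were examined and no test of them was run. The mast-like cells of the stomach included a cluster of 151 cells, all from that library and 7.79% of its mast-like cells, led by Speer4e: 500 of the 539 Speer4e UMIs of the stomach library lay in it and the other libraries had 0, although reads of the near-identical Speer4 family are uncertain. A cluster of 26 cells, 20 from stomach and 6 from small intestine, carried both mast cell and B cell transcripts and was left unnamed. A cluster of 126 cells, 75 from stomach, 12 from small intestine, 9 from cecum and 30 from colon, was led by S100a9, S100a8 and Retnlg, markers of neutrophils. At least 50% of its cells carried Csf1r, a macrophage and monocyte marker, while fewer than 50% carried S100a8 or S100a9. It was therefore left unnamed by the rule on lineages. A single stomach cell of a T-like cluster held 498 UMIs of Chga, a protein of hormone-secreting cells, with 276 of Clps, 19 of Ghrl and 1 of the Cd3 genes among its 6159 UMIs, and all other cells together held 4 Chga UMIs.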

How the results depend on the processing

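Settings named here as added after the result was seen are the UMI floor, the doublet score limit, the 20 most abundant genes, the cell with the most UMIs, genes that differ alike in other classes, and the dividing B-like cluster. No paired analysis was possible because each tissue had 1 library, and for the same reason no result had a test: a value is called moved where it left the 95% interval of the reported one, which for medians is an interval over genes and otherwise one of counting error. Few cells limit the stomach T-like values (249 cells) and the colon B-like values (204 cells). Limits on mitochondrial UMIs removed no cell, so those settings act through the gene count alone. Unless stated, the cause of a move was not tested.

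The T-like share rose from stomach to small intestine, cecum and colon in that order under all 11 settings, but single shares moved. At resolution 0.5 the T-like share was 75.3% in small intestine and 88.0% in colon, and the NK/ILC1-like share of stomach 14.98%. At resolution 2.0 the stomach T-like share was 5.67% and NK/ILC1-like 14.5%, dendritic-like cells were 7.79% of small intestine and B-like cells 13.8% of cecum. With 1000 variable genes T-like cells were 4.89% of stomach, 73.3% of small intestine and 87.2% of colon, and NK/ILC1-like cells 15.2% of stomach; with 4000 the stomach values were 4.98% and 15.2%, and B-like cells were 13.8% of cecum. With all barcodes T-like cells were 74.6% of small intestine and 87.6% of colon, and NK/ILC1-like cells 15.1% of stomach. With at least 500 genes T-like cells were 6.05% of stomach, 75.3% of small intestine and 87.9% of colon, and NK/ILC1-like cells 14.9% of stomach. With Scrublet calls kept T-like cells were 5.22% of stomach, 73.6% of small intestine, 78.6% of cecum and 86.1% of colon, and NK/ILC1-like cells 15.2% of stomach. With each library clustered on its own T-like cells were 73.8% of small intestine and 85.8% of colon, and mast-like cells 57.5% of stomach. From marker UMIs per cell T-like cells were 9.84% of stomach, 65.0% of small intestine, 75.5% of cecum and 78.3% of colon. With the added floor of 1581 UMIs T-like cells were 5.76% of stomach, 74.8% of small intestine and 87.4% of cecum, mast-like cells 52.4% and NK/ILC1-like cells 19.5% of stomach, and B-like cells 6.01% of cecum. With the top 3% of doublet scores removed, T-like cells were 5.97% and NK/ILC1-like cells 15.4% of stomach.

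For stomach against small intestine the median absolute log2 ratio was 0.50 with cells thinned, 0.43 with T-like cells from marker UMIs, 0.48 with Scrublet calls kept, 0.47 with at least 500 genes, 0.55 with Trdc cells alone, 0.58 with Cd8a cells alone, 0.52 at 200 CPM or more and 0.47 without genes that differ alike in other classes. For small intestine against colon it was 0.30 with cells thinned, 0.30 with Cd8a cells alone, 0.30 at 20 CPM or more and 0.30 at 200. For cecum against colon it was 0.16 after TMM scaling, 0.18 with cells thinned, 0.22 with Trdc cells alone, 0.20 with Cd8a cells alone and 0.19 at 200 CPM or more. For B-like cells without the dividing cluster it was 0.26. TMM factors were 0.997, 0.994, 1.02 and 0.986 for stomach, small intestine, cecum and colon.

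Some log2 ratios of genes turned direction. In stomach against small intestine, marker UMIs gave −4.60 for Ube2c, −1.39 for Nusap1 and −1.72 for Cd74. Scrublet calls kept gave −0.95 for Gzmc, −0.38 for Klra9 and −0.29 for Ube2c, and at least 500 genes gave −0.81 for Gzmc, −0.84 for Ncr1 and −0.43 for Ube2c. Trdc cells alone gave −1.43 for Trac, 0.52 for Trdc, −0.24 for Gzmc, −0.54 for Stmn1, −0.41 for Ube2c, −1.15 for Nusap1 and −0.74 for Cd74. Cd8a cells alone gave −0.47 for Gzmc, 0.51 for Gzmk, −0.37 for Ifit1, −2.63 for Stmn1, −1.39 for Ube2c, −0.30 for H2-Q6 and −0.025 for Cd74. Choosing cells by Trdc acts on the Trdc value itself. Those settings left 40 (Trdc) and 51 (Cd8a) stomach cells. In small intestine against colon, the mean over cells gave 0.069 for Tnfrsf9 and 0.37 for Cd74, and thinning gave 0.24 for Tnfrsf9 and 0.45 for Cd74. For Cd74 marker UMIs gave 3.55, Scrublet calls kept 1.10, at least 500 genes 0.75 and Trdc cells alone 0.86. Cd8a cells alone gave −0.30 for Foxp3 and 0.56 for Ifng. In cecum against colon, Cd74 was at 1.04 with marker UMIs, 1.05 with Scrublet calls kept, 1.01 with at least 500 genes and 1.07 with Trdc cells alone. Trdc was at 0.046 with Trdc cells alone.

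Of the reported genes and list members, TMM scaling left 100 of 100, 87 of 87 and 78 of 93 within their interval in the 3 comparisons, in the order of the text. Leaving out ribosomal, mitochondrial, immunoglobulin and receptor genes moved 0 of 98, 0 of 85 and 0 of 91. No Rpl, Rps or mitochondrial symbol was listed, so that step tested little beyond immunoglobulin and receptor genes. Leaving out the 20 most abundant genes moved 1, 9 and 0. Marker UMIs moved 42, 11 and 8 without a change of direction, Scrublet calls kept 39, 14 and 7, at least 500 genes 31, 11 and 6, thinning 26, 21 and 38, the mean over cells 11, 15 and 18, and leaving out the top cell of each gene 11, 3 and 1. Trdc cells alone moved 58, 61 and 50, and Cd8a cells alone 63, 37 and 45; a few genes had no value there. Of 60 list medians, 0 moved under TMM scaling and 2 among T-like cells without epithelial UMIs (215, 1499, 2603 and 2027 cells). Receptor shares moved for 17 of 20 without thinning and 19 of 20 with at least 2 UMIs; for Trdc these shares were 68.2% and 33.1% in small intestine, 15.1% and 7.12% in cecum and 27.3% and 13.5% in colon, and the thinning and the UMI minimum lower them by construction.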

Other observations

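The patterns tested here were noticed after the data were examined, and their tests were chosen then; each prediction was written before its test was run. Mast-like cells differed between libraries in the proteases they carried. In stomach (1939 cells) Mcpt2 stood at 64051 CPM and Mcpt1 at 32362, with Cma1 at 12705, Tpsb2 at 11216 and Cpa3, the mast cell carboxypeptidase, at 6608. In small intestine (64 cells) Mcpt1 stood at 61449, Mcpt2 at 53885, Cma1 at 6940, Tpsb2 at 4990 and Cpa3 at 4043. In cecum (28 cells) Mcpt1 stood at 101580, Mcpt2 at 52456 and Cpa3 at 2615, with 0 UMIs of Cma1 and of Tpsb2, which allows up to 37.2 CPM. The cecum cells all lay in 1 cluster, which also held 37 stomach cells, and outside stomach the class stayed below the 100 cells set for a comparison. All 5 genes are also markers of the class. Reads shared between the related genes Mcpt1 (chromosome 14, 56017964 to 56020391) and Mcpt2 (chromosome 14, 56021584 to 56044635) were not examined, so their split may be uncertain.

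A set of 12 genes was far lower in T-like, NK/ILC1-like, B-like and macrophage-like cells of stomach than of small intestine: Scand1, Taf10, Dapk3, Smap1, Tmem160, Pcbd2, Imp3, Hic1, Lars2, Chic2, Gimap1 and Pdcd2. In mast-like cells, not used to choose the set, the median log2 ratio was −3.29 (interquartile range −4.12 to −3.17). That was the result predicted if a different mix of T-like cells was not the source. The test adds little, since the set was already chosen to be low in NK/ILC1-like, B-like and macrophage-like cells, which a mix of T-like cells does not touch. GC content could not be told apart from other causes, since 33.3% (9.92–65.1%) of the set lay among the most GC-rich 20% of transcript ends and 12 genes are too few. A different gene annotation of the stomach library stays open. Of 3540 symbols at 50 CPM or more in the T-like cells of each of the other libraries, the stomach list lacked 1, Gm156. That gene led a T-like cluster that held 2 of the 249 stomach T-like cells, so its absence says little about the annotation. A biological difference between the tissues was not tested.

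Heat-shock and immediate early transcripts were higher in stomach than in small intestine T-like cells, with a list median of 1.18. Within the T-like cluster that held most stomach cells (184 against 147 cells) the median was 0.47 (interquartile range −0.04 to 0.97), 0.396 of the whole. This was the result predicted for a different mix of T-like clusters. The clusters were drawn from transcripts of the same cells, so holding the cluster fixed can lower the list's ratio whatever the cause. Another T-like cluster had Hspa1a, Hsph1 and Hspa1b among its leading genes. It held 0.803% of stomach and 0.777% of small intestine T-like cells, so its share hardly differed. No conclusion is drawn. Tissue handling that acted on the whole stomach library could not be told apart from a tissue difference: the medians were 0.33 in B-like, 0.39 in NK/ILC1-like and 0.40 in macrophage-like cells, between the values set for and against it, and 0.17 (interquartile range −0.68 to 0.73) in mast-like cells, which the test did not include. A response of the gastric T cells themselves stays open and was not tested.

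Oxidative phosphorylation transcripts were lower in cecum than in colon T-like cells, with a list median of −0.49. Transcript length was that of the longest annotated transcript of each gene, which may not be the one expressed. By that measure lower recovery of short transcripts is argued against, since the list lay at −0.50 relative to genes matched on transcript length. The median over all genes was 0.04 for the shortest 20% and 0.06 for the longest. The lengths of the transcripts expressed in these cells were not tested. Whether the difference spans the whole library could not be told apart from one of T-like cells: the list's median was −0.12 (interquartile range −0.62 to 0.21) in B-like, −0.39 in NK/ILC1-like and −0.64 in macrophage-like cells, and the B-like members go both ways. A difference between cecum and colon tissue may also account for it and was not tested.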
